A study of Homo sapiens with 36 samples.

How the data were processed

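RNA from human umbilical vein endothelial cells (HUVEC) was measured on 36 Illumina bead arrays. There were 3 experiments, each on a separate array chip per the labels. Per the series text, each had its own HUVEC donor and its own donor of panel-reactive-antibody (PRA) serum. Each experiment held 4 groups of 3 arrays: PRA serum, complement-inactivated PRA serum (heat-treated, per the labels), non-PRA serum, and vehicle, the gelatin veronal buffer in which the sera were diluted 1 to 10. Per the labels, PRA serum came from pre-transplant patients and non-PRA serum from healthy donors. Cells were treated for 4 hours. Every array took its group, experiment and replicate number from its label, and no array was moved or left out of the planned fit.

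The deposited non-normalized tables held the bead intensity of each probe on a linear scale for all 36 arrays. For experiments 1 and 2 they also held, per the file headers, a detection p-value for each probe, which behaved as the share of negative control beads at least as bright. The table of experiment 3 held no detection p-values. A further deposited table held intensity values processed by the authors, on a linear scale, with medians that were nearly equal within each experiment; the processing software was not given in the sources used here. That table served only as an alternative. Array chip, experiment and donor pair coincided, so differences between experiments include all 3.

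Of 47321 probes in common, 30113 carried 1 gene symbol, 8 carried several and 17200 carried none. Only probes with 1 symbol were used for genes, and 144 probes of XIST or Y-linked genes were left out. The symbols came from the supplied platform annotation; genomic positions were not used here. Background was corrected with the normexp method of limma and an offset of 16, using the detection p-values, followed by log2 transformation and quantile normalization of all 36 arrays. For experiment 3 the background mean came from the 25335 probes that were detected on no array of experiments 1 and 2. Their SD was multiplied by 1.13, the mean ratio found where both could be computed. On experiments 1 and 2 this substitute missed the background mean by at most 0.497 intensity units. A probe was kept when its detection p was under 0.01 on at least 3 arrays, with the rank among the 25335 undetected probes standing in for the detection p in experiment 3. This kept 19949 probes, and the brightest probe of each symbol gave 11414 genes. Detected probes made up 32.1% to 36.4% of all probes on the arrays of experiments 1 and 2, and 33.5% to 36.3% by the substitute in experiment 3. The substitute was more lenient: on experiments 1 and 2 it detected 36.7% on average, against 33.8% by the deposited detection p-values. The number of arrays limits the precision of every value.

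Before the data were examined, the following were fixed: the 6 comparisons, the planned fit, the alternatives, 24 gene lists and the rule for named genes. The planned fit averaged the 3 arrays of each group in each experiment and fitted the 12 means with limma (lmFit and eBayes), with experiment as a block, which left 6 residual degrees of freedom. P-values were adjusted over all 11414 genes by the Benjamini-Hochberg method, with a threshold of 0.05. Each experiment was also fitted alone on its 12 arrays, and the difference of each effect between experiments was tested with an interaction term. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 24 lists. Differences of lists between experiments were adjusted over 25, the 24 and a joint set of NF-kB and chemokine genes, formed after the data had been seen. R 4.3.3, limma 3.58.1 and matplotlib 3.10.9 were used.

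The 24 lists were leukocyte adhesion molecules, chemokines, cytokines and growth factors, NF-kB components and feedback genes, interferon-stimulated genes, antigen presentation genes, complement components and regulators, immediate early genes, coagulation and fibrinolysis genes, vascular tone and flow-responsive genes, serum response factor and YAP target genes, BMP and Notch target genes, sterol and lipid synthesis genes, unfolded protein response genes, heat shock genes, oxidative stress and metallothionein genes, hypoxia and glycolysis genes, p53 target and apoptosis genes, cell cycle genes and endothelial identity genes, and markers of smooth muscle and fibroblasts, leukocytes, erythroid cells and platelets, and epithelium. The rule named, for each comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign in all 3 experiments, or, where fewer than 10 passed, the 10 genes with the smallest p, plus list members. Uncharacterized symbols were passed over.

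A further reading was added only after the data had been seen, when the arrays of experiment 1 proved not to group by their labels. Experiments 2 and 3 were each fitted alone, and a gene was counted when it passed the threshold in both with the same sign. The naming rule was then applied to these genes, ranked by the mean of both log2 fold changes. The adjusted p-values within an experiment measure only the spread of its arrays: they share a cell donor, and those with PRA serum share a serum donor. Whether the 3 arrays of a group came from separate cultures was not given in the sources used here. A gene found in both experiments 2 and 3 was therefore seen with 2 donor pairs.

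Equal replicate numbers did not pair arrays: after removal of group means, arrays with the same number had a mean correlation of -0.0252 in experiment 2 and -0.000951 in experiment 3. None of the 630 array pairs was identical, and arrays of a labelled set of 3 correlated at 0.987 to 0.998. The fits were tested on simulated data with 200 changed genes among 11414. The planned fit recovered 74.6%, 98.5% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 10 false calls. A fit within 1 experiment recovered 76.1%, 100% and 100%, with 8 false calls. The simulation had no mixed labels and took its spread from experiments 2 and 3 alone. Its recovery therefore does not hold for the planned fit of the real data, which included experiment 1. Alternatives covered the background correction, the normalization, the probe filter and probe choice, the unit of replication, the blocks, the eBayes options, the threshold, the set test and the leaving out of each array, replicate number or experiment.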

Results

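The data were 36 genome-wide expression arrays of HUVEC, a primary endothelial cell, exposed for 4 hours to buffer with or without human serum. PRA serum carries antibodies against the HLA molecules of many other people, and non-PRA serum carries few. The series title states the purpose as the effect of alloantibody and complement on these cells. Each of 3 experiments held 3 arrays of each of 4 groups: PRA serum, complement-inactivated PRA serum, non-PRA serum and vehicle. Median probe intensity ran from 95.5 to 101 in experiment 1, from 108 to 114 in experiment 2 and from 107 to 117 in experiment 3. Fold changes below are on the log2 scale.

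SELE, which encodes the endothelial adhesion molecule E-selectin, showed how the experiments compared. In experiment 2 its normalized log2 level was 12.81 ± 0.05 (SD, n = 3) with PRA serum and 6.59 ± 0.13 (SD, n = 3) with vehicle. In experiment 3 it was 12.97 ± 0.10 (SD, n = 3) with PRA serum and 6.40 ± 0.26 (SD, n = 3) with vehicle. In experiment 1 the arrays labelled PRA serum gave 7.56 ± 2.31 (SD, n = 3), and those labelled vehicle gave 12.83 ± 1.52 (SD, n = 3). HSPA1A, an inducible heat shock chaperone, ran the other way: 6.12 ± 0.24 with PRA serum and 12.26 ± 0.20 with vehicle in experiment 2 (SD, n = 3). Its values in experiment 1 were 9.95 ± 1.88 on arrays labelled PRA serum and 6.27 ± 0.21 on arrays labelled vehicle (SD, n = 3). The nearest array by correlation had the same label for 12 of 12 arrays in experiments 2 and 3 each, and for 3 of 12 arrays in experiment 1. Across genes, which are not independent replicates, the PRA serum against vehicle change correlated at 0.828 between experiments 2 and 3. The same correlation was -0.737 between experiments 1 and 2 and -0.745 between experiments 1 and 3.

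**Figure D1:**
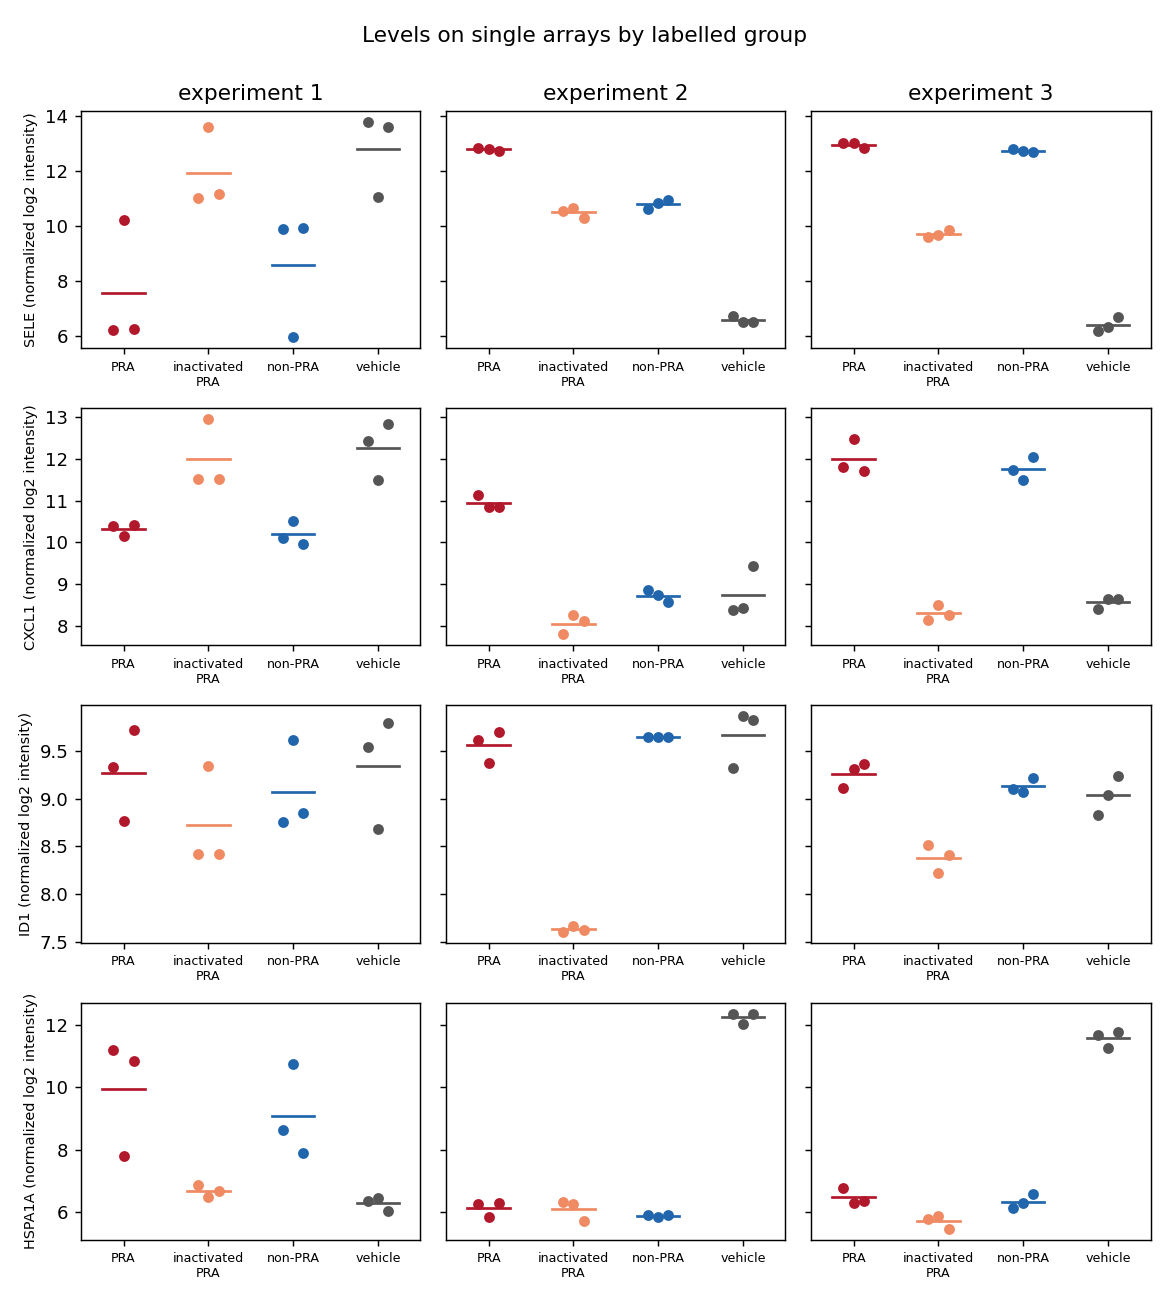
Normalized log2 intensity of SELE, CXCL1, ID1 and HSPA1A on each array (points), by labelled group and experiment, with the mean of each set of 3 arrays as a bar. In experiments 2 and 3 the PRA serum and vehicle arrays lay apart for SELE, with PRA serum means of 12.81 and 12.97 and vehicle means of 6.59 and 6.40; in experiment 1 the arrays of a label spread widely.

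In the planned limma fit of the 12 means over 3 experiments, 0 of 11414 genes passed the threshold in each of the 6 comparisons. The number with an unadjusted p under 0.05 was 491 for PRA serum against complement-inactivated serum, 143 for PRA against non-PRA serum and 602 for PRA serum against vehicle. It was 1044 for complement-inactivated serum against vehicle, 928 for non-PRA serum against vehicle and 287 for complement-inactivated against non-PRA serum, where chance alone gives 570.7. A limma fit of single arrays with experiment as a block called 71, 0, 273, 1203, 811 and 0 genes in the same order. With experiments 2 and 3 alone, that fit called 1353, 93, 5290, 4611, 5039 and 158 genes. It counts arrays that share a donor pair as replicates. The fit of means with experiments 2 and 3 alone called 0, 0, 3304, 2491, 3016 and 0 genes. Without experiment 1, genes thus passed that fit only in the comparisons with vehicle. Within experiment 1 limma called 6, 0, 19, 0, 21 and 4 genes, and with 1 array left out 0 to 36, 0, 0 to 1819, 0, 0 to 1256 and 0 to 6. Because 0 genes passed over 3 experiments, the account of genes below rests on experiments 2 and 3, a choice made after the data had been seen. A gene is said to have risen or fallen there when it passed in both, and pairs of values give experiment 2 first.

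PRA serum was compared with the same kind of serum after heat inactivation, which is meant to remove complement activity and leave antibodies in place. Neither activity was measured on these arrays, so loss of complement and other effects of heat on serum cannot be told apart. SELE rose by 2.31 (SE 0.11) in experiment 2 and 3.25 (SE 0.12) in experiment 3, which is 4.95-fold and 9.53-fold (3 arrays against 3 in each). The neutrophil chemokine gene CXCL1 rose by 2.88 (SE 0.22) and 3.68 (SE 0.19), and IL6, a pro-inflammatory cytokine gene, by 2.15 (SE 0.09) and 2.58 (SE 0.09). TSC22D3, a glucocorticoid-induced gene, fell (-1.36 and -1.45), as did TXNIP, which encodes a thioredoxin inhibitor (-2.18 and -1.02). On arrays labelled with these groups in experiment 1 the values were -4.37 for SELE, -1.67 for CXCL1 and 0.50 for TXNIP.

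Of 19 measured chemokine genes 10 rose and 0 fell, among them CCL20 (2.04 and 2.42), CXCL2 (1.40 and 2.57) and CXCL8 (1.13 and 1.26), which attract leukocytes. Of 30 NF-kB components and feedback genes 15 rose and 0 fell. They included NFKBIZ (1.53 and 2.53; another probe of this gene had the opposite sign in 2 vehicle comparisons), TNFAIP2 (1.38 and 1.52) and the feedback inhibitor gene TNFAIP3 (0.82 and 0.95). Of 20 cytokine and growth factor genes 4 rose: IL6, BMP2 (0.85 and 0.75), CSF3 and IL1A. Of 10 leukocyte adhesion genes SELE, ICAM1 (1.31 and 1.62) and VCAM1 (0.72 and 0.89) rose and 0 fell; the median of that list was -0.01 and -0.03 while its mean was 0.39 and 0.50. Of 15 BMP and Notch target genes 6 rose, among them ID1 (1.94 and 0.88), ID2 (1.00 and 0.88) and ID3 (0.98 and 0.85), and NOTCH4 fell (-0.48 and -0.98). HEY1 of that list rose, with the opposite sign on another probe. For ID1 the level with complement-inactivated serum was below vehicle, while that with PRA serum was near vehicle. On the arrays of experiment 2 ID1 was 7.60 to 7.67 with complement-inactivated serum, 9.38 to 9.71 with PRA serum and 9.33 to 9.87 with vehicle. In experiment 3 it was 8.22 to 8.52, 9.11 to 9.37 and 8.83 to 9.24 in that order. Of 25 named genes with several probes in this comparison, 10 had under 50% of the change, or the opposite sign, on another probe. Adjusted over the list alone, the counts were 10 of chemokines, 16 of NF-kB genes, 6 of cytokine genes, 6 up with 1 down of BMP and Notch targets and 3 up with 1 down of adhesion genes. They were 4 up with 1 down of vascular tone genes, 3 up of oxidative stress genes and 1 up with 2 down of p53 and apoptosis genes.

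With camera and an estimated correlation, the adjusted p was 0.00759 and 0.000324 for chemokines and 0.00927 and 0.00626 for NF-kB genes. It was 0.0142 and 0.00626 for cytokines, and 0.0236 and 0.018 for BMP and Notch targets. Immediate early genes, with 4 rises (EGR1, JUNB, IER3, DUSP5) and 2 falls (GADD45A, GADD45B) among 30, shifted up with the preset correlation in both. Their adjusted p was 0.0649 and 0.215 with an estimated correlation. Unfolded protein response genes differed between the experiments: 9 of 21 were higher in experiment 2, such as DDIT3 (1.68; 0.02 in experiment 3), and 0 were higher in experiment 3. The test of that difference gave an adjusted p of 0.00643 with an estimated correlation.

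Further large rises were TNFAIP6 (1.96 and 2.52), which encodes a secreted hyaluronan-binding protein, CYP4B1 (1.89 and 2.23), SLC25A24 (1.74 and 2.02, opposite on another probe) and F3 (1.81 and 2.03). F3 encodes tissue factor, the starter of coagulation, and was the 1 riser among 15 coagulation and fibrinolysis genes. Further falls were PDK4 (-1.47 and -0.93), GJA4 (-0.94 and -1.35), ZBTB16 (-1.17 and -1.02), MYLIP (-1.22 and -0.79), ADM (-0.79 and -1.29), MMP28, CHST15 and LRATD2. Of vascular tone genes 3 of 20 rose, among them PTGS2 (0.73 and 0.55), and ADM fell. In the other lists few genes moved: 2 of 21 SRF and YAP targets, 2 of 18 oxidative stress genes, 1 of 24 antigen presentation genes and 1 of 21 endothelial identity genes (S1PR1) rose. MYLIP of 23 sterol genes, ADM of 19 hypoxia genes and BCL2L1 of 17 p53 and apoptosis genes fell. Among interferon-stimulated genes (34 measured), complement genes (12), heat shock genes (16) and cell cycle genes (28), 0 passed in both experiments. The same held for markers of smooth muscle and fibroblasts (9), leukocytes (10), erythroid cells and platelets (4) and epithelium (6).

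In all, 257 genes passed in both experiments with the same sign, 157 up and 100 down, and 9 passed with opposite signs; independent calls would share 29.1. Experiment 2 called 844 genes and experiment 3 called 794, and the changes correlated at 0.471 across genes. The effect differed between experiments 2 and 3 for 280 genes by the interaction test, SELE among them (adjusted p 0.00209). The count in experiment 2 was 548 without complement-inactivated replicate 1 and 484 without replicate 2. In experiment 3 it was 510 without complement-inactivated replicate 2 and 482 without PRA replicate 3. In the planned fit the genes with the smallest p, none past the threshold, were GRK2 (-0.42, SE 0.06), MEG3 (-0.67, SE 0.13), MPDU1, SFT2D2, FRS3, MAP7D1, NPIPB5, SRRD, ZNF296 and RPL23AP87.

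PRA serum was compared with non-PRA serum, a contrast between sera rich and poor in alloantibody. The former came from pre-transplant patients and the latter from healthy donors, so antibody content and serum source cannot be told apart. CCL20, a chemokine gene, rose by 1.78 (SE 0.17) in experiment 2 and 0.62 (SE 0.11) in experiment 3 (3 arrays against 3 in each). RCAN1, a calcineurin feedback regulator gene, rose by 0.76 (SE 0.07) and 0.57 (SE 0.08). TIAM2, a Rac exchange factor gene, rose by 0.53 and 0.81, and GUCY1A1, a subunit of the nitric oxide receptor, by 0.33 and 0.53. FGFR3 fell (-0.46 and -0.68), with the opposite sign on another probe. Between arrays labelled with these sera in experiment 1 the values were -0.58 for CCL20 and -0.38 for RCAN1.

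In experiment 2 SELE changed by 2.01 (SE 0.11), CXCL1 by 2.22 (SE 0.22), IL6 by 1.87 (SE 0.09), F3 by 1.95 (SE 0.09) and NFKBIZ by 1.64 (SE 0.12). In experiment 3 the values were 0.23, 0.23, 0.12, 0.00 and 0.10, none past the threshold, and each of these differences between experiments passed the interaction test. Of 30 NF-kB genes 17 were higher in experiment 2 and 0 in experiment 3; of 19 chemokine genes 10 and 1 were higher. The test of the difference gave an adjusted p of 0.000449 for NF-kB genes and 0.000124 for chemokines, both with an estimated correlation. In experiment 2 alone 11 of 30 immediate early genes, 9 of 21 unfolded protein response genes, 7 of 20 cytokine genes and 3 of 10 adhesion genes were also higher. Their differences between experiments had adjusted p values of 0.00212, 0.00123, 0.00638 and 0.0145 with an estimated correlation. EGR1, an immediate early transcription factor gene, had opposite signs: 0.84 (SE 0.13) and -0.76 (SE 0.08), both past the threshold. Markers of smooth muscle and fibroblasts, leukocytes, erythroid cells and platelets, and epithelium held 0 genes that passed in both experiments.

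Camera called 0 lists in both experiments with the same direction. Immediate early genes were called up in experiment 2 and down in experiment 3 (adjusted p 8.7e-11 and 0.0046; 0.0359 and 0.296 with an estimated correlation). In this comparison 5 genes passed in both with the same sign, 4 up and 1 down, and 5 more with opposite signs. Independent calls would share 0.457 with the same sign. Of the genes called in experiment 2, 55.4% had the same sign in experiment 3. Of those called in experiment 3, 50% had the same sign in experiment 2, so direction did not repeat between the experiments. Adjusted over the list alone, CCL20 was the 1 chemokine that passed in both, with 1 up and 1 down of BMP and Notch targets, 1 down of sterol genes and 1 up of unfolded protein response genes. Experiment 2 called 496 genes and experiment 3 called 22, the changes correlated at 0.0845 across genes, and 321 genes differed between the experiments. Without non-PRA replicate 2 or 3 the experiment 2 count was 328 or 329. Without PRA replicate 3 or non-PRA replicate 2 or 3 the experiment 3 count was 9, 6 or 8, and the number shared was 2, 1 or 2. The number shared was also 2 without PRA or non-PRA replicate 1 of experiment 3, and 3 without PRA replicate 2 of experiment 3 or without PRA replicate 1 or 2 or non-PRA replicate 1 or 3 of experiment 2. With only the compared groups in the fit it was 0, so that all 5 calls were lost. In the planned fit the smallest p belonged, without passing the threshold, to PREX1 (-0.31, SE 0.07), MYLIP (-0.72, SE 0.17), DPH3, ZDBF2, PRRT2, SNORD17, FAM162A, F8A3, RNF185 and TAPT1.

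Complement-inactivated PRA serum was compared with non-PRA serum, a contrast of heat-treated, antibody-rich serum from patients with untreated, antibody-poor serum from healthy donors. Heat treatment, antibody content and serum source cannot be told apart in it. Some BMP and Notch target genes were lower with complement-inactivated serum. ID1, a transcriptional inhibitor gene induced by BMP signals, changed by -2.02 (SE 0.13) in experiment 2 and -0.75 (SE 0.11) in experiment 3 (3 arrays against 3 in each). ID2 (-1.15 and -0.47), ID3 (-1.01 and -0.64), the inhibitory SMAD gene SMAD6 (-1.23 and -0.45) and ATOH8 (-1.06 and -1.09) also fell. HEY1, a Notch and BMP target, fell (-0.90 and -0.53), with the opposite sign on another probe. Between arrays labelled with these sera in experiment 1 ID1 differed by -0.35 and ATOH8 by 0.50.

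Of 15 BMP and Notch targets 6 thus fell and 0 rose, or 7 fell when adjusted over the list alone. That adjustment also gave 4 falls of immediate early genes, 1 each of cytokine, SRF and YAP and oxidative stress genes, and 1 rise each of adhesion and NF-kB genes. Camera with an estimated correlation gave an adjusted p of 0.00454 in experiment 2 and 0.00601 in experiment 3. SPRY4, a feedback inhibitor gene of growth factor signalling, fell (-0.82 and -1.37), as did CMTM8 (-0.76 and -0.41) and NPTX1 (-0.57 and -2.28). TXNIP rose (1.43 and 0.94), as did PDK4 (0.63 and 1.12), a kinase gene that restrains glucose oxidation. The fall of BMP and Notch targets was itself smaller in experiment 3, with a median difference of 0.45 and an adjusted p of 0.00724 with an estimated correlation. Adhesion, cytokine and immediate early genes also differed between the experiments (0.0112, 0.0133 and 0.049), as did NF-kB and chemokine genes. In experiment 3, 17 of 30 NF-kB genes and 11 of 19 chemokine genes were lower with complement-inactivated serum, such as NFKBIZ (-2.43, SE 0.08) and CXCL1 (-3.45, SE 0.19). In experiment 2, 0 of either list passed, with NFKBIZ at 0.11 and CXCL1 at -0.67. The differences had an adjusted p of 7.6e-05 for NF-kB genes and 4.0e-06 for chemokines, with an estimated correlation.

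In this comparison 11 genes passed in both experiments, 2 up and 9 down, and 6 passed with opposite signs; independent calls would share 1.28. Experiment 2 called 54 genes and experiment 3 called 515, and 329 differed between them. Leaving out any 1 of the 6 arrays of experiment 2 gave 27 to 33 genes: 33, 29 and 31 without complement-inactivated replicates 1, 2 and 3, and 27, 31 and 27 without non-PRA replicates 1, 2 and 3. In experiment 3 the count was 309 without complement-inactivated replicate 1 and 342 without non-PRA replicate 3. In the planned fit the smallest p, none past the threshold, belonged to RPL23AP87 (-0.43, SE 0.08), IGBP1P1 (-0.49, SE 0.10), NACA4P, PREX1, MCTS1, RPL23AP64, UQCRHL, RPS28, KDM4B and PIGV.

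Each serum was compared with vehicle, the control for any effect of serum itself. With PRA serum SELE rose by 6.22 (SE 0.11) in experiment 2 and 6.57 (SE 0.12) in experiment 3 (3 arrays against 3 in each). It also rose with complement-inactivated serum (3.91 and 3.32) and with non-PRA serum (4.21 and 6.35). VCAM1, an adhesion molecule gene, rose by 2.90 and 2.76 with PRA serum, by 2.17 and 1.87 with complement-inactivated serum and by 2.06 and 2.63 with non-PRA serum. Among the largest falls were some heat shock genes, which encode chaperones, some metallothionein genes, whose proteins bind zinc and copper, and SNORD3 small nucleolar RNAs. With PRA serum HSPA6 changed by -7.07 (SE 0.18) and -5.37 (SE 0.09), and MT1M by -6.54 (SE 0.10) and -4.89 (SE 0.07). By the labels of experiment 1 the PRA serum values were -5.26 for SELE, 3.84 for HSPA6 and 1.49 for MT1M.

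Some heat shock and metallothionein genes fell with every serum. With PRA serum 5 of 16 heat shock genes and 9 of 18 oxidative stress and metallothionein genes fell. With complement-inactivated serum 6 and 8 fell, and with non-PRA serum 6 and 9 fell. The medians of the whole lists with PRA serum were -0.33 and -0.17 for heat shock genes and -0.18 and -0.30 for oxidative stress and metallothionein genes, and camera with an estimated correlation gave an adjusted p of 0.103 and 0.0284 for the former and 0.0719 and 0.0357 for the latter. With PRA serum the changes of these lists differed between experiments, with an adjusted p for the difference of 0.0361 and 0.00465 with an estimated correlation. HSPA1A changed by -6.14 and -5.12 with PRA serum, by -6.17 and -5.89 with complement-inactivated serum and by -6.40 and -5.26 with non-PRA serum. MT1X changed by -4.43 and -3.51, by -4.77 and -4.09, and by -4.56 and -3.82 in the same order, and the zinc exporter gene SLC30A1 by -3.89 and -3.73 with PRA serum. Members of these families have like sequences, so that their probes may not tell them apart, which also holds for SNORD3A, SNORD3C and SNORD3D, small nucleolar RNAs. With PRA serum SNORD3A changed by -5.41 and -4.57, SNORD3C by -5.69 and -4.73 and SNORD3D by -5.63 and -4.64. For 16 heat shock, oxidative stress, metallothionein and SNORD3 genes picked because they fell with every serum, the median change ran from -4.13 to -3.59 over 6 normalizations.

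Immediate early genes, which respond within minutes to stimuli, fell more often than they rose. Of 30, 15 fell and 5 rose with PRA serum, 17 fell and 3 rose with complement-inactivated serum, and 14 fell and 4 rose with non-PRA serum. FOS fell (-3.21 and -4.24 with PRA serum), while EGR1 rose (2.94 and 1.32). Cell cycle genes also fell: 11 of 28 with PRA serum, such as MKI67 (-0.76 and -0.81) and CCNE1 (-1.42 and -0.95), 8 with complement-inactivated serum and 10 with non-PRA serum, and 0 rose. Among 21 SRF and YAP targets 5, 6 and 5 rose and 0 fell, among them FILIP1L (2.51 and 2.05 with PRA serum) and TGFB2 (1.79 and 2.24).

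NF-kB genes rose with PRA serum, 20 of 30 with 3 falls, against 12 rises and 5 falls with complement-inactivated serum and 9 rises and 4 falls with non-PRA serum. The non-PRA count was held down by experiment 2, with 10 rises against 19 in experiment 3, and the difference between experiments had an adjusted p of 0.000667 with an estimated correlation. MAP3K8 changed by 3.17 and 3.36, by 2.19 and 1.41, and by 1.81 and 3.29 in that order, and the NF-kB subunit gene RELB by 2.48 and 2.22, 1.92 and 1.58, and 1.70 and 2.10. Of 19 chemokine genes 11 rose and 1 fell with PRA serum, 4 rose and 2 fell with complement-inactivated serum, and 4 rose and 1 fell with non-PRA serum. With non-PRA serum 4 rose in experiment 2 and 11 in experiment 3, a difference with an adjusted p of 6.8e-05. CXCL1 rose by 2.19 and 3.42 and CCL20 by 2.80 and 3.82 with PRA serum. IL6 rose with PRA serum (1.37 and 1.74) and fell with complement-inactivated serum (-0.78 and -0.85). With PRA serum 7 of 20 cytokine genes rose and TNFSF10 fell. CD55 and CD59, which shield cells from complement, were the 2 genes of 12 complement components and regulators that rose with each serum, CD59 by 0.97 and 1.12 with PRA serum.

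Other large rises shared by the sera were FBXO32 (3.51 and 3.75 with PRA serum), a ubiquitin ligase gene, ARID5B (3.48 and 3.35), the amino acid transporter gene SLC7A2 (3.20 and 3.25) and SNORA12 (2.88 and 2.59). ARRB1 (2.33 and 2.71), RGCC (2.83 and 1.72), PPP1R16B (2.29 and 2.46) and CCNG2 (2.11 and 1.94) were among the 10 largest rises with complement-inactivated serum, ARRB1 with the opposite sign on another probe. Markers of other cells moved little. With PRA serum PDGFRA (0.68 and 0.46) rose among 9 smooth muscle and fibroblast markers, and among 10 leukocyte markers GNLY (0.33 and 0.94) rose and CD14 (-0.78 and -0.46) fell. Of 4 erythroid and platelet markers and 6 epithelial markers 0 passed in both experiments with any serum.

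With the preset correlation, camera called 8 lists in both experiments with PRA serum: chemokines, cytokines, NF-kB genes and SRF and YAP targets up, and immediate early, heat shock, oxidative stress and cell cycle genes down. It called 6 with complement-inactivated serum and 4 with non-PRA serum. With an estimated correlation all of these calls were lost in experiment 2, with an adjusted p for PRA serum of 0.0719 for NF-kB genes, chemokines, cell cycle genes and oxidative stress genes, 0.103 for heat shock genes, 0.208 for immediate early genes, 0.245 for cytokines and 0.334 for SRF and YAP targets. The lowest such adjusted p in experiment 2 was 0.0954 with complement-inactivated serum and 0.115 with non-PRA serum.

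In all, 2613 genes passed in both experiments with PRA serum (1151 up, 1462 down), 2124 with complement-inactivated serum (1030 up, 1094 down) and 2407 with non-PRA serum (1141 up, 1266 down). The balance was not firm: rises were 51.1% with PRA serum under median scaling, and 53.8% and 53.4% with the other sera without replicate 2. Independent calls would share 738, 497 and 636, and 39, 19 and 40 genes passed with opposite signs. Experiment 2 called 4365, 3779 and 3855 genes, and experiment 3 called 3791, 2999 and 3745. The interaction test found 612, 376 and 597 genes that differed between experiments 2 and 3. These comparisons share the vehicle arrays, so part of their likeness may come from the shared arrays. In the planned fit the smallest p, none past the threshold, belonged to BACH2 (0.48, SE 0.09) with PRA serum, SFT2D2 (-0.46, SE 0.06) with complement-inactivated serum and ADGRL1 (0.39, SE 0.06) with non-PRA serum. Leaving aside genes with provisional open reading frame names, MEX3B was among the 10 smallest in each (0.59, 0.73 and 0.61). The others were ASB6, CDC42EP3, GABRE, KLHL13, PBXIP1, PGA3, PML and TEF with PRA serum, and ADGRL1, KBTBD8, SLAIN2, SLC4A2, TAOK2, YAF2, ZMYND8 (opposite on another probe) and ZNF296 with complement-inactivated serum. With non-PRA serum they were BATF3, KLHL13, PML, RBM38, SOCS1, TMEM51, WSCD1 and YAF2.

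**Figure D2:**
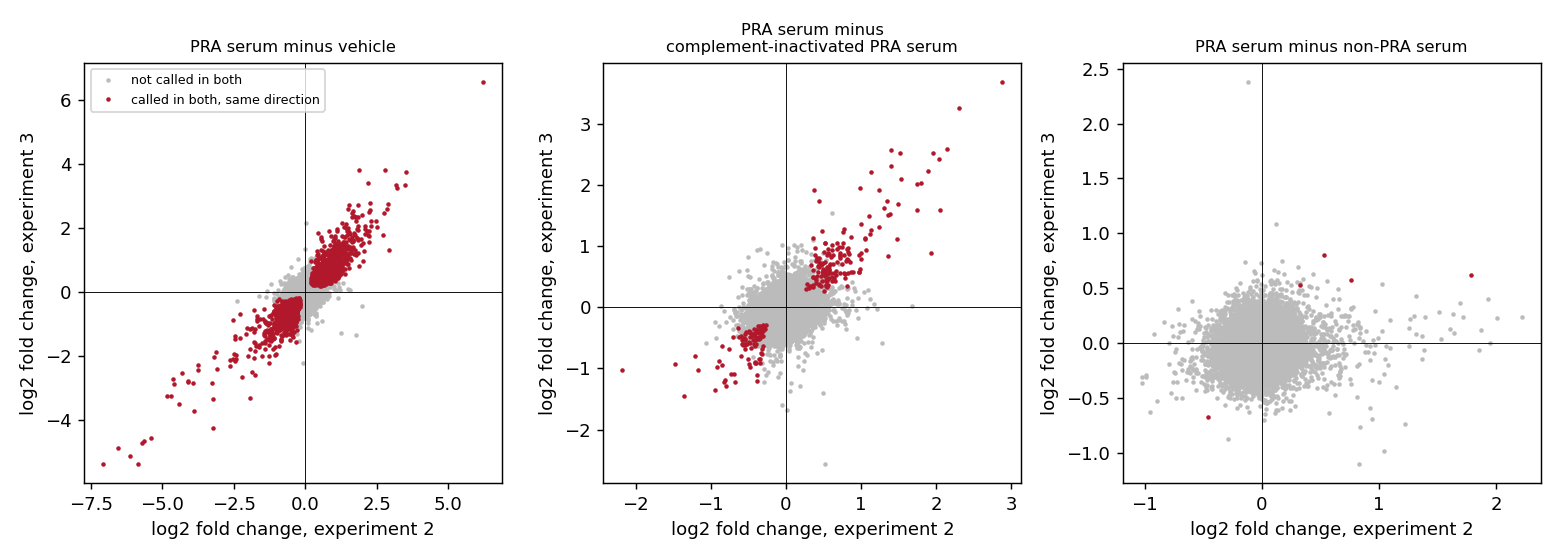
Log2 fold change of 11414 genes in experiment 2 (horizontal) against experiment 3 (vertical) for PRA serum against vehicle, complement-inactivated PRA serum and non-PRA serum; points are genes, red where a gene passed in both with the same sign. The 2613 and 257 red genes of the first panels lie along the diagonal, and the last panel has 5.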

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

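The tests of the experiment 1 arrays, of small RNAs, of mixed-up sera and of the non-PRA serum were chosen after the result was seen, as were all counts over both experiments 2 and 3.

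Each set of 9 arrays with the same label was examined, for 56 named genes and for percent detected, background and median intensity, for an array far from the other 8. Such an array was found in 28 of 236 sets, where chance gives about 1 in 20, or 11.8, if the sets are independent. They are not, since the genes were read on the same arrays, so 11.8 is only a rough guide. All 28 lay in experiment 1, and 27 of them in complement-inactivated or non-PRA serum. For SELE and MT1X the array was replicate 2 in both of these groups. For complement-inactivated serum the gap to the nearest array, as a share of the range, was 0.556 for ADM, 0.499 for ARID5B, 0.738 for CCL20, 0.741 for F3, 0.616 for FILIP1L, 0.690 for LRATD2, 0.501 for MT1G, 0.678 for MT1M, 0.571 for MT1X, 0.607 for SELE, 0.577 for TIAM2, 0.802 for TNFAIP6 and 0.528 for VCAM1. For non-PRA serum it was 0.517 for ARID5B, 0.597 for CCNG2, 0.801 for FBXO32, 0.505 for FILIP1L, 0.650 for FOS, 0.705 for MT1G, 0.907 for MT1H, 0.712 for MT1M, 0.860 for MT1X, 0.656 for MYLIP, 0.665 for PPP1R16B, 0.573 for SELE, 0.547 for SNORA12 and 0.514 for TXNIP. For vehicle it was 0.521 for GUCY1A1.

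Arrays of experiment 1 did not group by their labels: 0 of 12 had both nearest arrays of the same label, against 12 in experiment 2 and 11 in experiment 3. Failed arrays are argued against, since the lowest mean correlation of an experiment 1 array with its nearest 2 was 0.466, above 0.309 and 0.390 in experiments 2 and 3. Cells that did not respond to serum are argued against too: the range of the serum response in experiment 1 was 1.03 times the smaller range of the other experiments, and SELE spanned 7.86 log2 units. What stays open is that arrays of experiment 1 may carry labels of other groups, since the 12 arrays formed 4 closed sets of 3 mutually nearest arrays and all 4 crossed labels. A difference of donors shared by the 3 arrays of a label is argued against, since it would leave those arrays alike. With each gene centred within its experiment, labelled sets had mean correlations of -0.0377 to 0.195 in experiment 1. The ranges were 0.426 to 0.867 in experiment 2 and 0.408 to 0.795 in experiment 3. No array was given another label, and no further biological explanation was tested.

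Some heat shock, oxidative stress and metallothionein genes and SNORD3 genes were lower with every serum than with vehicle in experiments 2 and 3, though with PRA serum the medians of the whole lists were only -0.33 and -0.17 (heat shock) and -0.18 and -0.30 (oxidative stress and metallothionein). Normalization is argued against as the cause of these calls, since the median change of the 16 genes, picked because they fell with every serum, was -3.59 under the normalization with the smallest fall. For the SNORD3 part, a higher share of non-polyadenylated RNA on vehicle arrays stays open: 125 other small RNAs had a median change of -0.0826 but went both ways (28 lower, 4 higher), 114 of them were dimmer than the median gene, and 26 of 41 histone genes, which mostly lack a poly(A) tail, fell too. Untreated cells were not analysed here, so a stress of serum-free buffer and a direct effect of serum both remain open, as untested.

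PRA serum against non-PRA serum called 496 genes in experiment 2 and 22 in experiment 3. A deviating array in experiment 2 is argued against, since the lowest count with 1 array left out was 328. A partial exchange of arrays between these 2 sera in experiment 3 is argued against, since the other splits of their 6 arrays called at most 1 gene. A complete exchange would reverse the signs and leave the count at 22, so the count cannot address it. Leaving out 1 array (at most 19 genes) would not undo an exchange. What stays open is that the non-PRA serum of experiment 3 may have acted more strongly on NF-kB and chemokine genes than that of experiment 2: against vehicle, 22 of 49 such genes had a higher change with non-PRA serum in experiment 3 and 0 a lower one, while with PRA serum 10 were higher and 3 lower. The donors of cells and of PRA serum both changed between the experiments, and the labels do not name the donors of non-PRA serum. The parts of cell and serum donors in the difference were therefore not tested.

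The effect of a comparison differed between experiments by an interaction test for many genes. Between the 3 experiments the counts were 709 for PRA against complement-inactivated serum, 25 for PRA against non-PRA serum, 4753 for PRA serum against vehicle, 1710 for complement-inactivated serum against vehicle, 4145 for non-PRA serum against vehicle and 243 for complement-inactivated against non-PRA serum. Between experiments 2 and 3 they were 280, 321, 612, 376, 597 and 329 in that order. The counts over 3 experiments used the labels of the experiment whose arrays did not group by them. For single genes those counts cannot separate mixed labels from a true difference between experiments. A difference shared by the arrays of a label is argued against as the only cause. Labelled sets of experiment 1 had mean correlations of only -0.0377 to 0.195, with each gene centred within the experiment. Of 4566 detected probes without a gene symbol, which no gene count above used, 20, 0, 252, 182, 219 and 0 passed in both experiments 2 and 3 in that order.

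Other splits of the samples into groups of the same size were fitted in the same way. For 3 against 3 there are 10 splits, too few for a share under 0.05. In the planned fit the real count was 0 in each comparison, so all 10 splits gave as many, and the highest other count was 3473 for PRA serum against vehicle and 0 elsewhere. Within experiment 1 the real counts were 6, 0, 19, 0, 21 and 4, in the order above, and the highest other counts were 0, 1173, 0, 3452, 0 and 0. Counts of 3473, 1173 and 3452 where the labels gave 0 point to a structure of the arrays that the labels of experiment 1 do not follow. Within experiments 2 and 3 the real split gave the highest count, as 1 of 10, and no other split called more than 1 gene.

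For genes passing in both experiments 2 and 3, 100 splits were drawn for each comparison, the real one included. Chance in the grouping of arrays within each experiment can be excluded for 5 counts, reached by the real split alone: 257 (highest other 0), 2613 (39), 2124 (0), 2407 (40) and 11 (0). The splits kept each donor pair together, so they do not address chance over donor pairs. Whether the 3 arrays of a group came from separate cultures is not known. If they did not, chance between cultures is not addressed either, for genes or for lists. The 39 and 40 match the genes of opposite sign, which a split with the labels exchanged in 1 experiment alone would count. For the counts of 257, 2124 and 11, 9, 19 and 6 genes passed with opposite signs. For the 5 genes of PRA against non-PRA serum, 2 of 100 splits gave as many, so the share was under 0.05. The count is weak: 5 more genes passed with opposite signs, and 0 were shared without any 1 replicate number. The other split with 5 matches those 5 genes, which a split with the labels exchanged in 1 experiment alone would count. The direction of these calls thus agreed no more often than it disagreed. For lists called over the 3 experiments the real counts were 2, 0, 1, 3, 1 and 2 and the highest others 8, 10, 10, 11, 7 and 8, reached or passed by 9, 10, 10, 9, 9 and 7 of the 10 splits, which again points to a structure of the arrays. For lists called in both experiments the real counts were 5, 0, 8, 6, 4 and 1 and the highest others 4, 1, 4, 3, 6 and 2. Chance in the grouping of arrays can be excluded for PRA against complement-inactivated serum and the 3 vehicle comparisons (1, 1, 1 and 2 of 100 splits). Still, another split gave 6 lists for non-PRA serum against vehicle, and the calls of the 3 vehicle comparisons were all lost with an estimated correlation. Such chance cannot be excluded for PRA against non-PRA serum (100 of 100) or complement-inactivated against non-PRA serum (11 of 100).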

How the results depend on the processing

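The tests chosen after the data had been seen were the alternatives to the counts over both experiments 2 and 3, the fit of their single arrays, and the backgrounds from undetected probes on all arrays and without detection p-values; the others were planned. No named gene reversed its direction on the probe used, but the balance of rises and falls did in the vehicle comparisons, as given below. For 542 genes called in both experiments, counted per comparison, 6473 of 7039 checks kept the call and 566 lost it; for the 60 genes with the smallest p over 3 experiments, 1062 of 1196 checks did not pass the threshold and 134 did. Other probes were compared apart from these checks: of 25, 4, 56, 47, 46 and 4 named genes with several probes, in the order below, 2, 1, 3, 4, 2 and 1 had the opposite sign on another probe, and 10, 2, 11, 14, 12 and 3 had that or under 50% of the change. The counts named below are in the order PRA against complement-inactivated serum, PRA against non-PRA serum, PRA serum, complement-inactivated serum and non-PRA serum against vehicle, and complement-inactivated against non-PRA serum. The cause was not tested, except that leaving out arrays and a higher fold minimum leave fewer arrays or genes by construction, and single arrays give more degrees of freedom than means. Only 32.1% to 36.4% of probes were detected over background on an array, so changes of the others could not be seen.

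The planned counts of 0 genes became 71 (PRA against complement-inactivated serum), 273, 1203 and 811 (PRA, complement-inactivated and non-PRA serum against vehicle) with single arrays and experiment as a block. With each group by experiment set as a random block they became 245 and 48 for complement-inactivated and non-PRA serum against vehicle. With experiment and replicate number together as a block they became 17 for PRA against complement-inactivated serum and 52, 751 and 411 for the vehicle comparisons. With single arrays of experiments 2 and 3 they became 1353, 93, 5290, 4611, 5039 and 158. Leaving out each experiment or replicate number gave 0 to 3304, 0 to 2491 and 0 to 3016 genes for the vehicle comparisons, the highest each without experiment 1, and 0 to 0 for the others.

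Genes passing in both experiments 2 and 3 were 387, 22 and 24 without background correction for PRA against complement-inactivated serum, PRA against non-PRA serum and complement-inactivated against non-PRA serum, from 257, 5 and 11. For PRA against non-PRA serum they were 8 with median scaling, 21 with the authors' values, 2 without a detection filter, 2 with all named probes, 3 with the replicate block, 0 with only the compared groups in the fit and 17 with trend and robust options. For complement-inactivated against non-PRA serum they were 22 with the authors' values and 23 with trend and robust options, and for PRA against complement-inactivated serum 161 with only the compared groups in the fit. With a change of at least 1.5-fold the counts were 84, 1, 916, 704, 804 and 6. The share of rises was 61.1% for PRA against complement-inactivated serum, with a range of 53.7% to 81.5% over the alternatives, 80% (52.9% to 100%) for PRA against non-PRA serum and 18.2% (16.7% to 50%) for complement-inactivated against non-PRA serum. For PRA serum against vehicle it was 44.0% (43.9% to 51.1%), with more rises than falls under median scaling. For complement-inactivated serum it was 48.5% (47.5% to 53.8%), passing 50% without replicate 1, 2 or 3, and for non-PRA serum 47.4% (46.2% to 53.4%), passing 50% without replicate 2 or 3. Leaving out each replicate or array gave 92 to 267, 0 to 4, 1503 to 2607, 1070 to 2004, 1349 to 2321 and 2 to 11 genes.

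Within experiment 1, leaving out 1 array gave 0 to 36, 0 to 0, 0 to 1819, 0 to 0, 0 to 1256 and 0 to 6 genes, from 6, 0, 19, 0, 21 and 4. Within experiment 2 it gave 484 to 977, 328 to 574, 3627 to 4864, 3086 to 3386, 3118 to 3343 and 27 to 33. Within experiment 3 it gave 482 to 804, 6 to 19, 3168 to 3484, 2327 to 2771, 3138 to 3502 and 309 to 411.

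Lists called over the 3 experiments, 2, 0, 1, 3, 1 and 2, were 0 in each comparison with an estimated correlation and 0 with fry; leaving out an experiment gave 2 to 7, 0 to 4, 2 to 7, 1 to 5, 3 to 6 and 0 to 5. Lists called in both experiments, 5, 0, 8, 6, 4 and 1, were 8, 2, 13, 13 and 11 with fry for all but the last comparison. With an estimated correlation they were 0 for the 3 vehicle comparisons. For PRA against non-PRA serum 1 list was called without background correction and 1 with the authors' values.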

Other observations

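The gene sets of histones and small RNAs were chosen after the data had been seen; the lists named here were planned, and their calls in both experiments 2 and 3 were read after the data had been seen.

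KLF2, a flow-induced transcription factor gene, changed against vehicle by -2.62 and -2.30 with PRA serum, by -2.86 and -2.63 with complement-inactivated serum and by -3.15 and -2.46 with non-PRA serum. Of 21 endothelial identity genes 4 fell and 0 rose with PRA serum, among them the tight junction gene CLDN5 (-1.35 and -1.19) and the transcription factor gene SOX18 (-0.85 and -1.02); with each of the other sera 4 fell and 1 rose. Camera called this list in neither experiment for PRA serum, with an adjusted p of 0.583 and 0.504 with an estimated correlation. Of 20 vascular tone and flow-responsive genes 3 rose and 5 fell with PRA serum, with PTGS2 higher (1.20 and 0.90) and HMOX1 (-1.39 and -0.96) and APLN (-1.05 and -1.96) lower. Hypoxia genes went both ways: NDRG1 (1.11 and 1.41) and KDM3A (1.54 and 1.36) rose and ADM (-1.28 and -2.21) fell with PRA serum, 4 rises and 2 falls among 19. Of 17 p53 and apoptosis genes 3 rose, such as PMAIP1 (1.42 and 1.39), and 2 fell.

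Interferon-stimulated genes also went both ways with PRA serum against vehicle, with 5 rises, such as OASL (0.43 and 1.04), and 5 falls, such as IFIT1 (-0.93 and -0.52), among 34. Of 24 antigen presentation genes CD274 (0.56 and 1.11) and ICOSLG rose. Of 23 sterol and lipid genes 2 rose and 2 fell, and of 21 unfolded protein response genes XBP1 (1.35 and 0.91) and DNAJB9 rose and TRIB3 fell. That list differed between the experiments, with 10 rises and 1 fall in experiment 2 and 2 rises and 5 falls in experiment 3 (adjusted p 0.00465 with an estimated correlation). Of 41 measured replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 26 were lower with every serum than with vehicle in both experiments and 0 were higher, with a median change of -1.11. Probes of these families share sequence, so single members may not be told apart; the same holds for heat shock, metallothionein and SNORD3 genes, of which 16 picked because they fell with every serum had a median change of -3.59 under the normalization with the smallest fall.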
